A study of Mus musculus with 6 samples.

How the data were processed

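RNA from immortalized mouse embryonic fibroblasts was sequenced in 6 libraries, 3 from wild-type cells and 3 from PME-1 knockout cells, with a kit that keeps strand, per the labels' protocols. The deposited values are raw read counts per gene symbol, 1 column per library, with 53762 genes. Trim Galore 0.6.6 and HISAT2 2.2.1 are named in the submitters' processing notes. The counting program, its strand setting and its annotation are not given in the sources used here. The notes name a human genome build although the symbols are mouse symbols, so no coordinates of the authors were used. Groups were taken from the sample titles, because the genotype cells of KO libraries 2 and 3 name other numbers after PME. Positions come from GENCODE M21 on GRCm38, in which 92.9% of the symbols were found by name.

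Total counts ranged from 34450993 to 44116310 per library. A floor of 3 counts is 0.068 to 0.0871 CPM. Counting intervals (95%, exact binomial on summed counts scaled by effective library size) and floors cover counting error only. No libraries were identical: the chi-square per degree of freedom was 13.41 between WT 2 and WT 3, 13.92 between KO 2 and KO 3, and 125.07 to 149.25 for pairs with WT 1 or KO 1, so each library was counted as 1 replicate.

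Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, robust quasi-likelihood fit, glmQLFTest) with Benjamini-Hochberg adjustment over 15223 genes and a threshold of 0.05. CPM values use TMM factors. The SE of a log2 fold change is its size divided by the square root of F. Gene lists, 50 in all and fixed with the design before the data were examined, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, variance trend, preset correlation 0.01) where at least 5 members were tested, which left 49 lists. All adjusted p-values of single genes come from edgeR and those of lists from camera unless another tool is named. Named genes are Ppme1, the 14 highest rises and the 14 deepest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups (unnamed gene models and pseudogenes left out), and up to 4 members of each list that camera called or that had at least 3 members past the threshold, with a mean of at least 1 CPM. A gene that this rule selects is not reported here. Genes outside this rule were chosen after their values were seen.

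Alternatives were DESeq2 1.42.0, limma-voom, median-ratio, upper-quartile and no scaling factors, no filter, a mean of at least 5 CPM, a test against a fold of 1.5, the replicate number as a block, each library left out in turn, an estimated correlation and fry for lists. Added after seeing the data were 1 surrogate variable (sva 3.50.0), leaving out both libraries numbered 1, counting only genes not placed on chromosomes 9, X and Y, and camera without Ppme1, without the genes of chromosome 9 and without both. Pseudogene transcripts were matched to coding transcripts with blastn 2.17.0 (E-value limit 1e-10), which found the gene in the name for 214 of 219 pseudogenes named after a tested gene. The tests were tried on simulated counts with 200 changed genes: for PME-1 KO against WT over 15223 genes, edgeR recovered 33 of 100 genes changed 2-fold and 87 of 100 changed 4-fold, with 8 false among 128 calls. The simulated genes varied independently of each other, so these rates leave out deviations that many genes share within a library.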

Results

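Gene expression was measured by RNA sequencing in immortalized mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, collected 24 hours after seeding. The 6 libraries fall into 2 groups, 3 from wild-type (WT) cells and 3 from cells without PME-1 (KO). PME-1, encoded by Ppme1, is the methylesterase that removes the methyl group from the catalytic subunit of protein phosphatase 2A (PP2A). The files hold raw read counts for 53762 mouse gene symbols. Total counts were 38155189, 43235450 and 44116310 in WT libraries 1 to 3 and 35497802, 43000426 and 34450993 in KO libraries 1 to 3. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Values are CPM, read counts scaled to the size of each library, as mean ± SD with n = 3 per group, and each log2 fold change (KO against WT) comes with its standard error (SE).

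Ppme1 transcripts were reduced in all 3 KO libraries but were not absent. The gene (ENSMUSG00000030718.9) lies on chromosome 7 from 100326737 to 100372307, on the minus strand, in the GENCODE M21 annotation of GRCm38. WT libraries held 2828, 3492 and 3774 Ppme1 counts and KO libraries held 705, 636 and 644. The level was 81.9 ± 4.22 CPM in WT and 17.4 ± 2.14 CPM in KO, a 4.72-fold lower level (log2 fold change -2.24, SE 0.13, adjusted p = 0.000563). Counts per gene do not show which exons the remaining reads cover, so they do not tell whether an intact transcript was left.

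The comparison of KO with WT asks how gene expression differs between cells without and with PME-1. Of 15223 genes tested, 540 rose and 587 fell in KO cells, 1127 in all, and 425 of the rises and 291 of the falls were at least 2-fold. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in every WT library and were at least 853-fold, 497-fold, 389-fold and 331-fold higher in KO, against a floor of 3 counts per library. Xist, the noncoding RNA of the inactive X chromosome, was at 431 ± 60.2 CPM in WT and 0.229 ± 0.0998 CPM in KO (adjusted p = 0.000102). All WT libraries thus carried Xist without Y-linked transcripts and all KO libraries the reverse, so sex markers and genotype separate the libraries in the same way in every count given here. DESeq2 called 2406 genes, and the count ranged from 332 to 1216 when 1 library was left out.

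**Figure D1:**
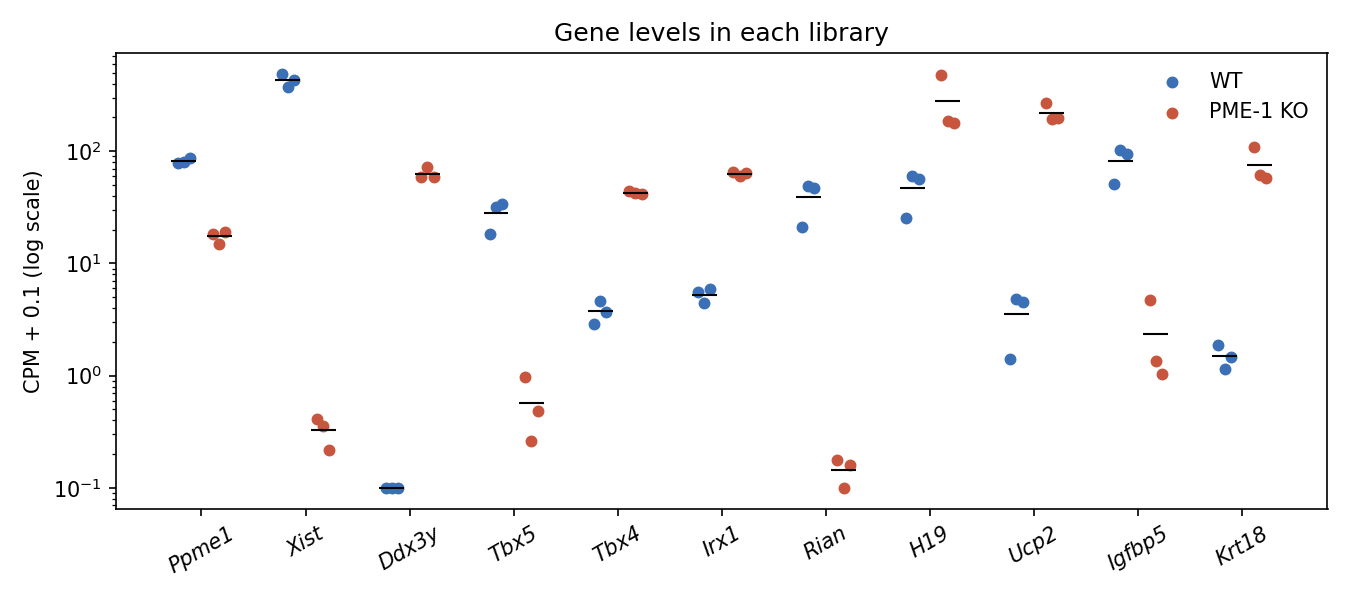
CPM plus 0.1 on a log axis for 11 genes in each of the 3 WT (blue) and 3 KO (red) libraries, with group means as black bars. Ppme1 lies at 81.9 CPM in WT and 17.4 CPM in KO on average, and Ddx3y has 0 counts in each WT library.

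Other large rises included Ucp2, a mitochondrial uncoupling protein, from 3.47 ± 1.88 to 219 ± 42.6 CPM (62.7-fold, adjusted p = 0.00183). Ucp2 lies 167 kb from Ppme1. Krt18, a keratin of simple epithelia, rose from 1.39 ± 0.369 to 75.5 ± 28.3 CPM (54.4-fold). The glycosyltransferase gene B3gnt3 rose 59.9-fold, the nuclear pore gene Nup210 48.3-fold, Gpx7 27.0-fold, Dkk3 25.3-fold, the lactate transporter Slc16a3 21.7-fold, the gap junction gene Gjb2 21.6-fold and Traf1 20.2-fold. Gpx7 was 47.8-fold higher without WT 2, Gjb2 48.7-fold without WT 1 and Slc16a3 14.4-fold without KO 1. Rbm20, a splicing regulator, had 4 counts over the WT libraries, all in WT 3, and 1710 over the KO libraries, a ratio of 455.4 with a 95% counting interval from 177.6 to 1673.5. Among the falls, Sox11, a transcription factor of progenitor cells, went from 45.7 ± 16.6 to 0.59 ± 0.152 CPM (77.0-fold, adjusted p = 0.000598). Igfbp5 fell 36.1-fold, Adra1d 23.7-fold, Csgalnact1 18.7-fold, Igfbp6 17.4-fold, Pcdhga3 14.2-fold, Galnt17 14.2-fold, and Gsc fell by 3.81 on the log2 scale, while Igfbp5 was 74.4-fold lower without KO 1. Mab21l1 had 1315 counts over the WT libraries and 4 over the KO libraries, 3 of them in KO 3, a ratio of 308.6 with a counting interval from 120.2 to 1134.2.

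Transcription factors that mark position in the embryo changed in both directions. Of 51 tested patterning factors, 12 rose and 12 fell (17 rose and 16 fell adjusted over the list alone). Tbx5, which marks the forelimb, fell 58.7-fold from 27.9 ± 8.32 to 0.475 ± 0.367 CPM (adjusted p = 0.00314), and 104-fold without KO 1. Tbx4, which marks the hindlimb, rose 11.7-fold from 3.64 ± 0.889 to 42.6 ± 1.61 CPM (adjusted p = 0.000563). Irx1 rose 12.2-fold and Foxd2 10.8-fold. Of 20 tested HOX genes, which set position along the body axes, 5 rose and 5 fell (6 rose and 5 fell adjusted over the list alone). Hoxd12 rose 9.14-fold (5.89-fold without KO 1), while Hoxd9, Hoxd10 and Hoxd8 fell 8.62-fold, 3.07-fold and 2.25-fold. Neither list was called by camera, with adjusted p = 0.596 for the patterning factors and 0.976 for HOX genes. Camera tests for a shift in a shared direction. Here and below it cannot decide whether a list with both rises and falls changed. Of 21 imprinted genes, 5 rose and 3 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.976). The noncoding RNAs Rian and Meg3, neighbours in an imprinted cluster of chromosome 12, had 5 and 3 counts over the KO libraries (all 3 of Meg3 in KO 3, and 0 of Rian in KO 2) against 4924 and 1051 over the WT libraries, ratios of 924.4 (counting interval 395.8 to 2848.2) and 328.8 (112.2 to 1597.1). Ndn and H19 rose 7.42-fold and 5.93-fold, H19 3.85-fold without KO 1. All 5 tested sex-linked markers passed, 4 higher and 1 lower, also when adjusted over the list alone, with a list median of 8.61 on the log2 scale when genes at 0 are placed at their bound (camera adjusted p = 4.19e-05; adjusted p = 0.68 with an estimated correlation).

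Targets of NF-kB, a transcription factor of inflammation, were higher in KO cells. Of 26 tested members 12 rose and 0 fell (19 rose adjusted over the list alone), and the list median was 1.07 (camera adjusted p = 1.92e-10; adjusted p = 0.0727 with an estimated correlation). Traf1, an adaptor of TNF receptors, rose from 0.525 ± 0.181 to 10.7 ± 3.85 CPM. The chemokine genes Ccl5, Cxcl5 and Ccl2 rose 9.16-fold, 4.39-fold and 4.08-fold, the last from 20.1 ± 1.24 to 82.2 ± 3.17 CPM, and Ccl5 rose 5.05-fold without KO 1. List medians relative to the mean of the 6 libraries were -0.61, -0.61 and -0.51 in WT and 0.58 in each KO library. Without WT 1 and KO 1, a choice made after seeing the data, 21 members rose and 0 fell. In that setting, here and below, genotype cannot be told apart from any difference of WT 1, KO 2 and KO 3 from the others.

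Genes of the interferon response and of MHC class I antigen presentation were called higher by camera, and libraries WT 1 and KO 1 stood apart from the others in both. Of 45 interferon-stimulated genes only Cxcl10 and Trim25 rose (8 adjusted over the list alone; camera adjusted p = 8.04e-07; adjusted p = 0.864 with an estimated correlation). Cxcl10, a chemokine, rose 8.10-fold and Trim25, a ubiquitin ligase, 6.27-fold. The list medians were -1.91, -0.2 and 0.02 in WT libraries 1 to 3 and 2.51, -0.14 and -0.22 in KO libraries 1 to 3. Of 20 antigen presentation genes, H2-Q7 rose by 4.25 on the log2 scale, H2-K1 and H2-D1 rose 5.89-fold and 3.08-fold and Tapbpl fell 2.11-fold (5 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0112; adjusted p = 0.909 with an estimated correlation). H2-Q7 has close paralogs, so its reads are uncertain, and its call was lost without KO 1 (log2 fold change 2.99, adjusted p = 0.0636) and without WT 2 (4.835, adjusted p = 0.121). The antigen presentation list was not called without WT 1 (camera adjusted p = 0.285) or without KO 1 (0.438), nor at a mean of at least 5 CPM (0.066), and the interferon median in the list test went from 1.328 to 0.508 without KO 1 and to 1.915 without KO 3. The medians of this list were -1.26, 0.03 and 0.12 in WT and 1.45, -0.14 and -0.14 in KO. Without WT 1 and KO 1 neither list was called, with list medians of -0.03 and -0.28 against 1.95 and 0.76 with all libraries.

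**Figure D2:**
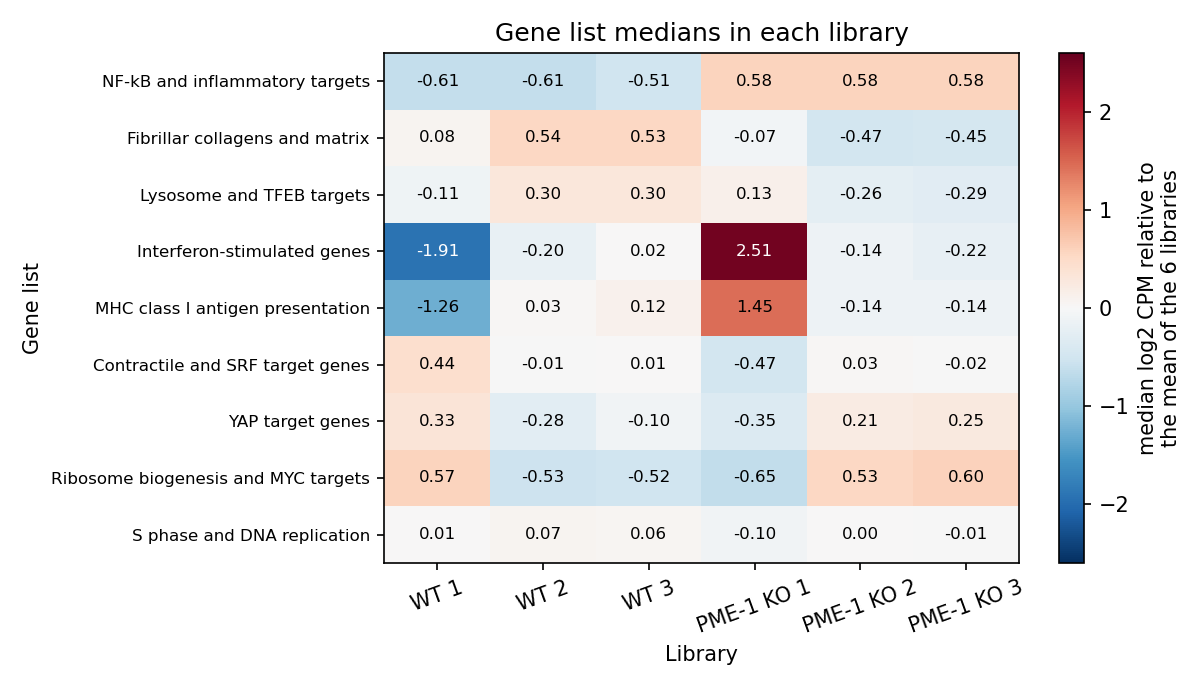
Median log2 CPM of 9 gene lists in each library relative to the mean of the 6 libraries, from blue (lower) to red (higher). NF-kB targets are at 0.58 in each KO library, while the interferon list is at -1.91 in WT 1 and 2.51 in KO 1.

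Genes of the fibroblast matrix were lower in KO cells. Of 47 collagens and matrix genes 13 fell and 1 rose (17 and 3 adjusted over the list alone), with a list median of -0.61 (camera adjusted p = 0.000218; adjusted p = 0.864 with an estimated correlation). Aspn, Fmod, Col11a1 and the proteoglycan gene Vcan fell 17.6-fold, 7.73-fold, 7.02-fold and 6.10-fold, Vcan from 464 ± 72.4 to 76.1 ± 19.9 CPM. Aspn fell 35.8-fold without KO 1, and Fmod was 13.4-fold lower without KO 2 but not called (adjusted p = 0.0524). The medians of the list were 0.08, 0.54 and 0.53 in WT and -0.07, -0.47 and -0.45 in KO, so WT 1 and KO 1 differed less than any other pair of a WT and a KO library. Of 21 basement membrane genes 3 fell and 1 rose (3 and 4 adjusted over the list alone; camera adjusted p = 0.976). Col4a1 and Col4a2, which form type IV collagen, fell 3.51-fold and 2.92-fold and Col18a1 2.24-fold, while the laminin gene Lama5 rose 3.15-fold. Of 30 matrix proteases and inhibitors 5 fell and 3 rose (8 and 3 adjusted over the list alone; camera adjusted p = 0.118, and 0.0137, lower, without WT 1 and KO 1). The gelatinase Mmp2 fell 5.71-fold and the collagen-processing Adamts2 4.08-fold, and Serpine2 and Mmp23 rose 10.3-fold and 6.71-fold. Without KO 1 Mmp23 rose 4.39-fold, and Serpine2 was 5.48-fold higher but not called (adjusted p = 0.06). Of 26 contractile genes Acta2, the smooth muscle actin, fell 7.14-fold from 411 ± 280 to 57.6 ± 29.7 CPM and Fhl2 fell 1.94-fold, also when adjusted over the list alone (camera adjusted p = 0.0112; adjusted p = 0.898 with an estimated correlation). The contractile list medians were 0.44, -0.01 and 0.01 in WT and -0.47, 0.03 and -0.02 in KO, and the call was lost without WT 1 and KO 1 together or without either (camera adjusted p = 0.309 without WT 1 and 0.271 without KO 1), and at a mean of at least 5 CPM (0.066). Without WT 1 Acta2 was 4.34-fold lower and not called (adjusted p = 0.0538).

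Receptors and ligands changed too. Of 23 receptor tyrosine kinases 6 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.00532; adjusted p = 0.358 with an estimated correlation). Ret, Pdgfrb and Fgfr2 fell 7.88-fold, 2.41-fold and 2.24-fold and Flt4 rose 5.84-fold (9.98-fold without WT 1). Of 40 axon guidance genes 5 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0294; adjusted p = 0.864 with an estimated correlation). Sema7a, Sema3a, Neo1 and Efnb1 fell 4.55-fold, 3.31-fold, 2.73-fold and 2.65-fold, and Sema7a and Neo1 lie in a run of lower genes on chromosome 9. Without WT 1 and KO 1 the receptor kinases and the axon guidance genes were not called (camera adjusted p = 0.0704 and 0.0883), nor the latter without WT 3 (0.0612), at a mean of at least 5 CPM (0.066) or without the genes of chromosome 9 (0.119). Of 37 growth factor ligands 5 rose and 6 fell (9 and 11 adjusted over the list alone; camera adjusted p = 0.976), with Fgf10 10.0-fold lower (17.8-fold without KO 2) and Nog, Areg and Pdgfb 8.42-fold, 3.92-fold and 3.18-fold higher. In the WNT list 1 of 25 rose and 3 fell (1 and 4 adjusted over the list alone; camera adjusted p = 0.596), namely Dkk3 and, lower, Lef1 (8.59-fold), Wnt5a (4.53-fold) and Lgr4 (1.65-fold). In the TGF-beta list 1 of 26 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.311), namely Tgfbr2 2.08-fold higher and Smad6 and Id3 1.95-fold and 1.91-fold lower, where Smad6 lies in the chromosome 9 stretch. Among 29 integrins and cadherins, Cdh11 fell 11.3-fold, Cdh10 rose 5.14-fold and Pcdh17, with 0 counts in each WT library, was at least 38.0-fold higher, from 213 counts in KO 1, 69 in KO 2 and 44 in KO 3 (2 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.444).

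The list of PP2A and its regulators, which holds Ppme1 itself, was called lower by camera, but not without Ppme1 (adjusted p = 0.106) or without the genes of chromosome 9 (0.191), both tried after seeing the data. Of 31 tested members 4 fell and 0 rose (5 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0355; adjusted p = 0.864 with an estimated correlation), with a median of -0.14. Besides Ppme1 these were Anp32a, Ppp2r3a and Arpp19, which fell 1.99-fold, 1.82-fold and 1.70-fold. Anp32a and Arpp19 are known as inhibitors of PP2A and Ppp2r3a as a regulatory subunit. All 3 lie on chromosome 9, where 16.8% of tested genes were called against 6.8% on the other autosomes. The stretch between 55 and 75 Mb of that chromosome (GRCm38) was chosen after seeing the data, for the low medians of its 5 Mb bins. In it 71 of 125 genes with a mean of at least 5 CPM were called lower, and the median log2 fold change was -0.81. Anp32a lies inside this stretch, and Ppp2r3a (101105084) lies past its end, in a bin with a median of -0.30. Arpp19 (75037614) starts just past the bin edge at 75 Mb and had a log2 fold change of -0.77. The bins before and after that edge had medians of -0.88 and -0.41. Without chromosome 9 the PP2A list median was -0.08, and without Ppme1 as well the adjusted p was 0.443. Without WT 1 and KO 1 the list was not called (adjusted p = 0.682), nor without WT 1 (0.0981), without KO 1 (0.262), at a mean of at least 5 CPM (0.128) or with library sizes alone as scaling (0.0649).

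**Figure D3:**
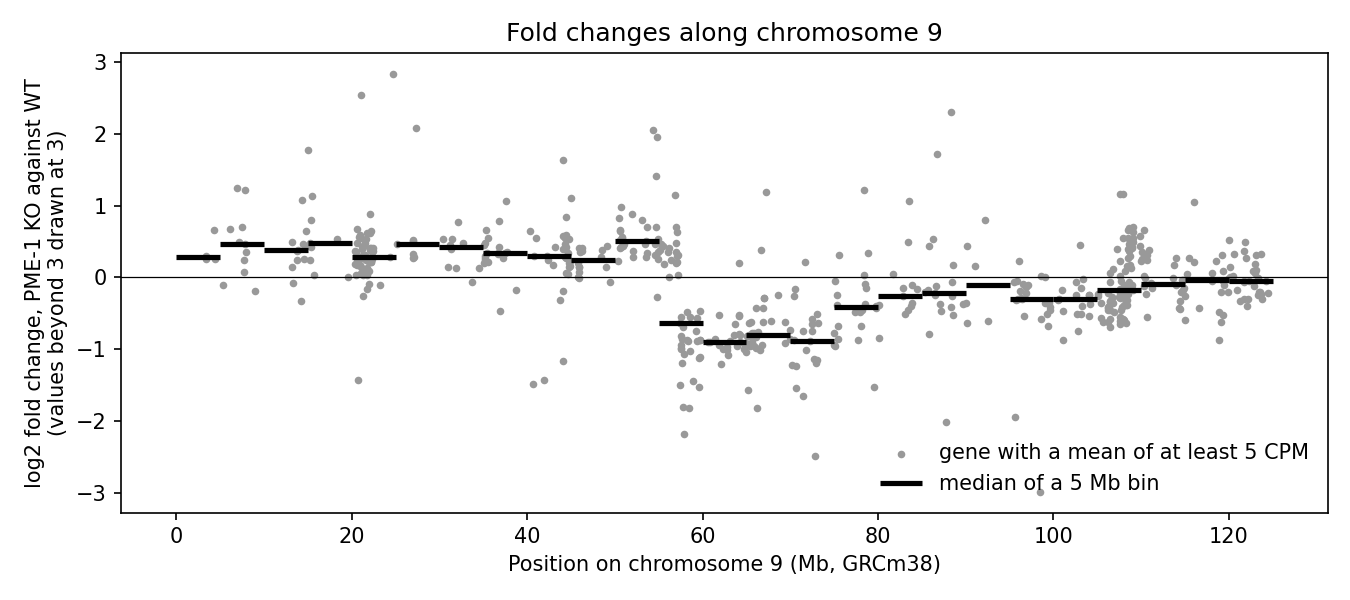
Log2 fold change of genes with a mean of at least 5 CPM against position on chromosome 9 (grey), with medians of 5 Mb bins as black bars. The median between 55 and 75 Mb is -0.81 and the median before 55 Mb is 0.36.

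In metabolism and stress lists few members passed. The ATF4 and amino acid list had 2 of 31 members higher, Stc2 (7.63-fold) and Atf3 (3.32-fold), with 9 rising adjusted over the list alone (camera adjusted p = 8.6e-06; adjusted p = 0.864 with an estimated correlation). Of 39 lysosomal genes Hexa, Tfeb and Lamp1 fell 2.89-fold, 1.60-fold and 1.45-fold and Rragd rose 6.25-fold, 3.90-fold without KO 1 (1 rose and 8 fell adjusted over the list alone; camera adjusted p = 0.00104; adjusted p = 0.864 with an estimated correlation), and Hexa lies in the chromosome 9 stretch. The lysosomal list medians were -0.11, 0.30 and 0.30 in WT and 0.13, -0.26 and -0.29 in KO, so WT 1 and KO 1 lay in the order opposite to the call. Without WT 1 and KO 1 the median of the log2 fold changes went from -0.31 to -0.59, and 31 members fell. Genotype cannot be told apart there from the difference of WT 1, KO 2 and KO 3 from the other libraries. Of 75 ribosomal protein genes 3 rose, also adjusted over the list alone, Rpl30, Rpl17 and Rplp0 (camera adjusted p = 8.04e-07; adjusted p = 0.864 with an estimated correlation). The ribosomal protein medians were 0.07 in WT 1 and 0.04 in KO 1, against -0.16 and -0.25 in the other WT and 0.10 and 0.18 in the other KO libraries. Rpl30, Rpl17 and Rplp0 have processed pseudogenes of matching sequence and are uncertain, since how the counting divided reads between them is not known. Summed with the pseudogenes matched to it, the Rpl30 family was at 312 ± 53.4 CPM in WT and 422 ± 59.8 in KO, a log2 ratio of 0.43 against 3.99 for Rpl30 alone. The ratios were 0.24 for the Rplp0 family and 0.12 for the Rpl17 family. Of 70 nuclear-encoded respiratory chain genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.695), namely Ndufs5 (2.36-fold), Atp5e (1.69-fold) and Sdhd (1.43-fold) higher and Cox5a (1.98-fold) lower. Ndufs5 has a pseudogene that fell and is uncertain too, and Cox5a lies in the chromosome 9 stretch. Sdhd lies on chromosome 9 before that stretch (50596357), with a log2 fold change of 0.52 in a bin with a median of 0.51. Of 24 YAP target genes Nt5e, Igfbp3 and Asap1 rose 4.94-fold, 4.38-fold and 1.68-fold, also adjusted over the list alone (camera adjusted p = 0.513, and 0.00032, higher, without WT 1 and KO 1). Of 22 senescence-related genes 4 rose and 2 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.976), with Igfbp4 4.71-fold higher. Among 33 cell death regulators Casp4 and Mlkl rose 12.3-fold (7.04-fold without KO 1) and 3.29-fold and Ripk3 fell 5.73-fold (3 and 2 adjusted over the list alone; camera adjusted p = 0.836), where Ripk3 and Mlkl act in necroptosis. Of 43 S phase genes 0 passed in edgeR (8 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with limma-voom), and of 45 mitotic genes 1 fell, Kif23, which lies in the chromosome 9 stretch.

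Markers of other cell types were mostly low. Of 14 tested epithelial markers Krt18 and Krt8 rose, the latter 14.9-fold from 0.229 ± 0.0383 to 3.44 ± 2.06 CPM (5 rose adjusted over the list alone; camera adjusted p = 0.000418; adjusted p = 0.318 with an estimated correlation). Of 10 neural and glial markers Sox2 rose 6.95-fold, Map2 fell 1.73-fold and 1 more rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.464). Of 5 endothelial, 7 skeletal muscle and 6 pericyte or mesothelial markers 1, 1 and 2 rose. Of 11 cartilage and bone markers 1 rose and 1 fell, and of 6 adipocyte and 4 leukocyte markers 0 passed in edgeR (1 and 0 at an unadjusted p under 0.05, and 1 and 0 with DESeq2).

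**Figure D4:**
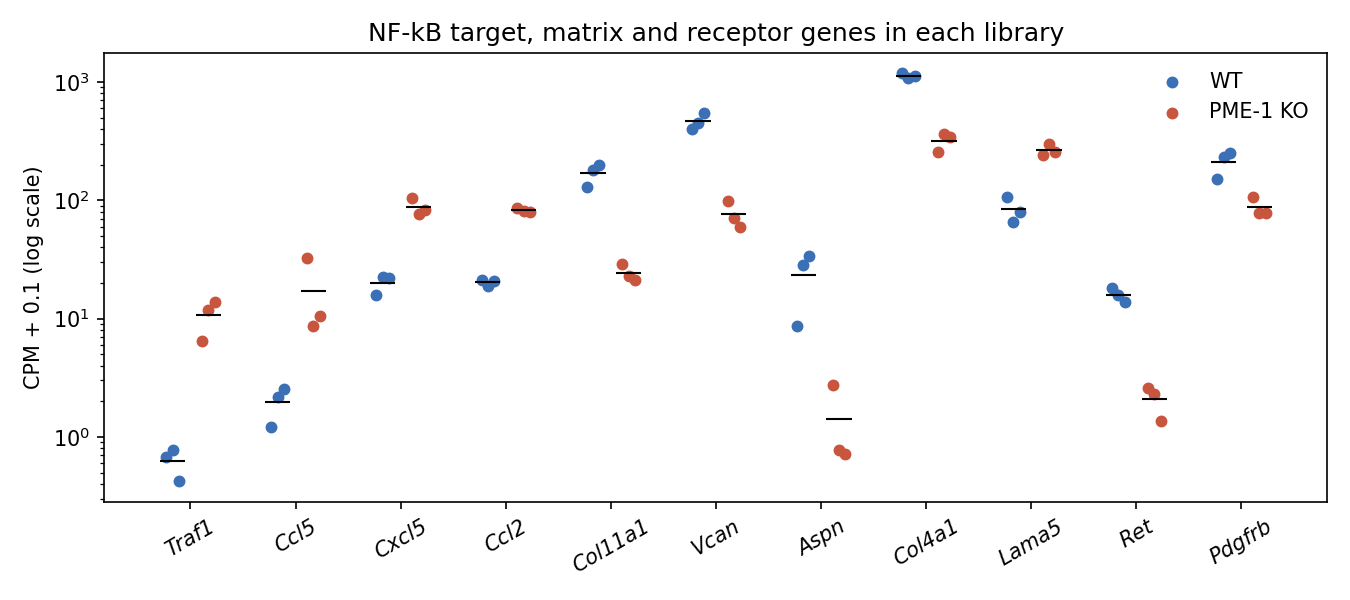
CPM plus 0.1 on a log axis for 4 NF-kB targets, 5 matrix genes and 2 receptor genes in each of the 3 WT (blue) and 3 KO (red) libraries, with group means as black bars. Ccl2 lies at 20.1 CPM in WT and 82.2 in KO on average.

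The lists were fixed before the data were examined. With a preset correlation of 0.01 between genes camera called 13 of 49 lists, and with a correlation estimated from these libraries it called 0 (3 at an unadjusted p under 0.05), where the smallest adjusted p was 0.0727, for NF-kB targets. The estimates for NF-kB targets, receptor kinases and epithelial markers were -0.017, -0.006 and -0.011. These lie below 0.01, so a higher correlation does not account for the loss of these calls. With fry their adjusted p were 9.27e-06, 0.00434 and 0.00197. The matrix, ATF4, ribosomal protein, lysosomal, interferon, contractile, MHC class I and PP2A lists, all called by camera, were not called by fry. Their fry adjusted p ranged from 0.0807 for PP2A to 0.575 for MHC class I. The median, the mean and the direction of the test differed in sign for the senescence, YAP, WNT, cell death, integrin and cadherin, HOX, imprinted, replication-dependent histone and leukocyte lists, of which camera did not test the last.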

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

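Leaving out both libraries numbered 1, the surrogate variable, the count outside chromosomes 9, X and Y and the list tests without Ppme1 or chromosome 9 were chosen after the data were seen. The count of 1127 changed genes (540 higher, 587 lower) became 2406 (1195 and 1211) with DESeq2, which made 49 false among 200 calls on simulated data, and 396 (229 and 167) when tested against a fold of 1.5, a stricter question. The simulated genes varied independently, so that share of false calls need not hold in these libraries. The count was 5409 (2554 and 2855) with 1 surrogate variable and 7408 (3605 and 3803) without both libraries numbered 1. In the latter the spread comes from WT 2 with WT 3 and KO 2 with KO 3 alone. Genotype there coincides with the split of WT 1, KO 2 and KO 3 against the other libraries, which called 2166 genes. Calls made in that setting, of genes and of lists, cannot be credited to genotype alone. Leaving out 1 library gave 332 to 1216 genes (170 to 556 higher, 162 to 660 lower): 385 without WT 2, 332 without WT 3, 375 without KO 2 and 359 without KO 3. The other settings gave 824 to 1179 genes, and 937 of the calls were not placed on chromosomes 9, X or Y, 909 of them placed elsewhere and 28 without a position. The share of higher genes was 47.9%, and 57.1% with library sizes alone. None of the 1127 genes changed sign under any of these settings where it was tested. With the replicate number as a block 8 genes (3 higher, 5 lower) were called, and Ppme1 was at -2.245 with an adjusted p of 0.0518. Libraries with the same number deviated from their group means with correlations of -0.51, -0.31 and -0.22, which gives no sign that the numbers pair the samples. The 3 values are not independent, since deviations within a group sum to 0 and WT 1 and KO 1 departed in opposite ways. They cannot exclude shared days or cultures. Of 108 named genes, 62 to 98 passed when 1 library was left out. With an estimated correlation camera called 0 of 49 lists against 13, and fry called 10, 5 of them among the 13. A mean of at least 5 CPM left 9 calls among 43 lists, 8 of them shared. Without the genes of chromosome 9 camera called 11 of 48 lists, and without Ppme1 12 of 49. Without both libraries numbered 1 the direction of camera's test turned for 2 of the 13 called lists, whose medians went from 0.669 to -0.281 for MHC class I and from -0.322 to -0.031 for contractile genes, and neither was called. Called in addition were YAP targets (adjusted p = 0.00032), matrix proteases (0.0137), heat shock (6.22e-07), ribosome biogenesis (1.16e-23) and autophagy (0.00662). The cause of these differences was not tested. Depth limits genes near the floor of 3 counts, and on simulated data 33 of 100 changes of 2-fold were recovered.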

Other observations

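Several HOX and patterning genes beyond those named by rule, chosen after their values were seen, also separated the groups. Hoxc9 and Hoxc10 had 0 counts in every WT library and were at least 9.50-fold and 22.3-fold higher in KO. Pitx1, a hindlimb gene, rose 3.20-fold, and Shox2, Lhx9 and Lhx2 fell 6.69-fold, 5.51-fold and 4.03-fold. In glycolysis 1 of 23 genes rose, Slc16a3, and 1 fell, Pkm, which lies in the chromosome 9 stretch (camera adjusted p = 0.188).

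Except for the glycolysis list, all tests in this part were chosen after the result they bear on had been seen. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 1127 genes and the highest of the others 2166, so 2 of the 10 splits gave as many, and the other one sets WT 1, KO 2 and KO 3 against WT 2, WT 3 and KO 1, which points to a structure of the samples other than genotype.

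Sex markers and limb genes separated the groups. A swap of libraries between the groups is argued against, since 0 of 6 libraries had a Ppme1 level on the side of the other group. Of the changed genes, 4.6% lie on X or Y. That share cannot decide whether dosage of X and Y accounts for the other changes, since dosage can also act on genes of other chromosomes. Genes of the patterning and HOX lists, fixed beforehand, were changed more often than other genes (34 of 71, odds ratio 11.8), which is consistent with cell lines of different embryonic position. That origin, a difference in sex and the loss of PME-1 cannot be told apart for these genes. Every WT library has the female markers and every KO library the male ones. Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in every WT library, and Xist was at 431 CPM in WT and 0.229 CPM in KO. These values argue against loss of PME-1 as the source of the sex markers. An effect of PME-1 on the patterning and HOX genes stays open and untested.

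On chromosome 9 the genes between 55 and 75 Mb had medians of -0.86, -0.75 and -0.77 in KO libraries 1 to 3 relative to the WT mean, while genes before 55 Mb had 0.29, 0.38 and 0.37. A copy-number difference between the cell lines may account for it. The bound asked for more than 80% of genes below the median of all genes, on both sides of the run's median expression. It was not reached by the lower-expressed genes, at 76.2%, but was by the higher-expressed genes, at 88.7%. The share in the whole run was 82.4%. Strain variants that keep reads from mapping stay open as well, with 78.4% of the genes below -0.3 (binomial 95% interval 70.2 to 85.3), against a bound of 75%. The stretch was picked for its bin medians of -0.63 to -0.9, so high shares of lower genes were fixed in advance. These shares, the interval and the bounds therefore cannot decide between the explanations. An effect of PME-1 loss was not tested. Smaller shifts lay on other chromosomes. Genes with a mean of at least 5 CPM had a median of -0.24 on chromosome 12 and 0.26 on chromosome 19, against -0.03 over all chromosomes. Leaving out chromosome 9 therefore does not remove every shift by position.

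WT 1 and KO 1 departed from their groups in opposite ways, among others in interferon, MHC class I and ribosome biogenesis genes. The medians of the last were 0.57, -0.53 and -0.52 in WT and -0.65, 0.53 and 0.6 in KO. Library size is argued against, as WT 1 and KO 1 differ by 27.5% of the range of total counts. A different share of dividing cells stays open, as the mitosis list differed by 0.37 between their deviations and the S phase list by 0.01 (quartiles over genes -0.23 and 0.3). Culture state such as density or feeding may contribute, with a difference of 0.52 for YAP targets, but no culture record sets these libraries apart, so it and an unlabelled batch cannot be told apart. No biological explanation from the design was tested.

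Within 500 kb of Ppme1, 7 of 19 tested genes were called, 36.8% against 7.4% elsewhere (Fisher's exact test, two-sided, p = 0.000271), among them Ucp2, 167 kb away. The test takes neighbouring genes as independent, which they need not be, so its p-value may be too small. Of these genes 4 rose and 3 fell. Among the rises, Dnajb13 and Gm35082 had 0 counts in each WT library, and Plekhb1 had 4 in WT 2 and 0 in the others. Gm8730, a pseudogene of Rplp0, fell from 963 ± 58.6 to 16.2 ± 5.17 CPM (n = 3), while Rplp0 rose from 1135 ± 69.6 to 2681 ± 98.5 CPM.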
